A study of Mus musculus with 12 samples.

How the data were processed

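Total RNA of C2C12 cells, turned into Cy3-labelled cRNA per the labels, was hybridised to 12 one-colour Agilent whole mouse genome arrays, 3 for each of the 4 stages. The authors deposited the scanner output of each array. Its intensity columns hold, per the file headers, the processed signal of each spot, with background subtracted and spatial trends removed by Agilent Feature Extraction, and the median pixel brightness of the spot and of its local background. Flags of 0 or 1 for spots well above background, saturated or outlying in their pixels or among replicate spots were, per the file headers, set by Feature Extraction. The headers give Feature Extraction version 10.1.1.1, the submitters' processing notes give 10.5.1.1; which version made the values stays open. The authors also deposited a table of log2 values. Set against the scanner output, its 41174 probes were the log2 median brightness minus the array's 75th percentile, centred on each probe's median over the arrays, with a median absolute difference of 0.00056 and 100% of values within 0.01. Its column medians were 0.55, 0.02 and 0.03 for the myoblast arrays, -0.12, -0.12 and -0.07 at T0, -0.27, -0.05 and 0.00 at 24 h, and -0.02, 0.14 and 0.30 for myotubes (replicates 1 to 3). A higher value means a brighter spot, so scale, centring and direction are settled.

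Control spots (1639 per array) and spots with an outlier flag (99 to 1306 per array) were left out, spots of one probe were averaged, and the log2 processed signal minus the array's 75th percentile was used. Outlier flags were far more frequent on slides 2 and 3, and 1071 tested genes lack at least 1 array. Saturated spots (0 to 9 per array) were kept. A probe was tested if it was well above background on all unflagged arrays, at least 2, of at least 1 stage, which kept 55.7% of probes (22952), and the brightest probe stood for each gene, leaving 17230 genes. The files carry no gene names: array identifiers were matched, without versions, to a RefSeq gene table (GRCm38.p6), used for names only. Of 33059 identifiers 17558 matched (53.1%), giving 17178 symbols; 11707 of the tested genes have one, and others keep the array's identifier. Of 4522 genes with more than 1 tested probe, probes gave opposite calls in 0, 0, 16 and 28 genes for T0 against myoblast, 24 h against T0, myotube against 24 h and myotube against myoblast.

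Models were fitted with limma 3.58.1 in R 4.3.3 with the package data.table (version 1.17.8) over all 12 arrays with 1 mean per stage, moderated with a trend in variance, and adjusted by Benjamini-Hochberg at 0.05. Sharing all arrays means that leaving out any array can move any comparison. Gene lists, 24 of them written before the data were examined, were tested with camera on moderated statistics with a preset inter-gene correlation of 0.01, adjusted over the 22 lists with at least 5 tested members and the 4 comparisons. A transient pattern needed a call in both steps, in opposite directions and each with a fitted change of at least 2-fold, so that a change known only as a bound can be smaller. A gene not well above background on any array of a stage has only a bound there: its fold is given as "at least", from the mean of the brighter stage against the mean of, per array, the higher of the lowest signal well above background and the probe's own. For named genes above background on 1 or 2 of 3 arrays of the dimmer stage, the fold computed with that stage's arrays raised to the same floor is given where it differs by over 1.5 times, and for Itgb1bp2 and Myom1. Named genes followed a rule fixed at the same time: the 5 largest rises and falls of each comparison among genes called, without overlap between the arrays of the stages (10% of unchanged genes would show none) and detected on all arrays of the brighter stage, leaving out unnamed clones. It added, for each shifted list, the 2 largest called members in the majority direction and the largest in the other, a panel of 20 genes, and the 6 transient genes of each kind whose smaller change was largest. Genes of lists chosen later appear in the closing observations.

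The labels describe the replicates as independent biological ones. Replicate numbers matched the slides, found from the scan information in the file headers, and scan day separated slide 1 from slides 2 and 3. Deviations from the stage means correlated, across genes, in all 18 same-numbered pairs of arrays (0.51 to 0.86). The 36 differently numbered pairs ran from -0.72 to 0.42 (median -0.555). Deviations sum to 0 within a stage, which by itself pushes these pairs below 0. Of the 36, 12 were over 0.1, those between replicates 2 and 3, so part of the structure sets slide 1 against the others. The numbers thus pair the arrays and coincide with the slides. Whether same-numbered arrays also shared a culture is not stated in the labels. The fit with the replicate number as a block, which is also the slide block, lowered the median residual SD from 0.54 to 0.26 and is quoted where it changes the call of a result given or moves a count by over 1.5 times. Replicates of a stage shared at most 1 identical value (correlation across probes 0.917 to 0.985). Of the 633, 674, 4382 and 6655 genes called in the 4 comparisons, 623, 660, 4344 and 6573 had values on all 3 slides, and 623, 660, 4343 and 6569 of these changed in the same direction on each slide. The genes were called on these same arrays, and a call favours 1 direction on every slide, so this agreement is not separate support.

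Alternatives tried were quantile normalization, scaling on the spike-in probes (320 spots per array) or on probes detected throughout, the deposited log2 table, no filter or a stricter one, the mean of a gene's probes, blocks for replicate and scan day, only the arrays compared, no variance trend, an estimated camera correlation, a minimum change of 0.5 (treat), and each array left out. Arrays were left out in fits without the block, so a missing array also unbalances the slides and lets the slide difference into a comparison. The planned normexp correction of the mean signal could not be run because the files hold no such column. Normexp (offset 50) on the median signal took its place. The spike-in level relative to the 75th percentile was 1.79 on myoblast replicate 1 and 0.42 to 1.03 on the other arrays.

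The code was tested on simulated data for 24 h against T0 with 16159 genes, T0 levels, slide effects and residual spread taken from the data and noise drawn independently for each gene. Of 67 genes changed 4-fold, 10.4% were called without and 98.5% with the block; of 67 changed 2-fold, 0% and 59.7%; of 67 changed 1.5-fold, 0% and 17.9%. Of 15958 unchanged genes, 0 and 10 were called. A list shifted by 0.5 was found in 20 of 20 simulations and 0 of 420 tests of other lists were called; since real genes vary together, this bears on independent noise alone. With the 24 h level set equal to T0 or to the myotube, 20 simulations each gave at most 0 transient rises and 1 fall in either fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.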

Results

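RNA of C2C12 cells, a mouse myoblast line that leaves the cell cycle and fuses into multinucleated myotubes when serum is lowered, was profiled on one-colour (Cy3) whole-genome microarrays at 4 stages. The stages were growing myoblasts, the start of differentiation (T0), 24 h after it and myotubes 96 h after it, with 3 arrays per stage described as independent biological replicates. The myotubes had been lifted with dilute trypsin from the undifferentiated reserve cells that remain in such cultures. The question was which genes change as the cells go from one stage to the next. Each array held 43379 spots other than controls, of which 52.1% to 62.5% were well above background, and the 75th percentile of the processed signal ran from 562.5 (myoblast replicate 1) to 1382 (24 h replicate 1). The number of arrays limits the precision. Replicate numbers coincided with slides: replicate 1 of every stage was on slide 1, scanned on another day than slides 2 and 3. Every stage also had the same position on each slide, so position and stage cannot be separated by a fit.

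Over the 4 stages, 6482 of 17230 genes changed (limma F test), and 13066 did so with the replicate number as a block. The first principal component, 54.5% of the variance of 16159 genes with a value on every array, ordered the arrays from myoblast to myotube. The second, 22.1%, set slide 1 apart from slides 2 and 3 at every stage. Scaling on the spike-in probes moved the median of all genes from -0.12 to 0.44 for T0 against myoblast, from -0.01 to -0.28 for myotube against 24 h and from -0.18 to 0.06 for myotube against myoblast, so directions are relative to the array's 75th percentile. Myoblast replicate 1, with a spike-in level of 1.79 relative to that percentile, weighs heavily in the moves against myoblast. Changes are differences of log2 level, 3 arrays against 3 unless stated, and the adjusted p-values are limma's. Each standard error comes from the moderated residual variance over all arrays of the fit, not from the spread of the arrays compared alone. That of the gene Myog was thus 0.66 at every step, although its SD was 1.4 in myoblasts and 0.09 in myotubes.

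**Figure D1:**
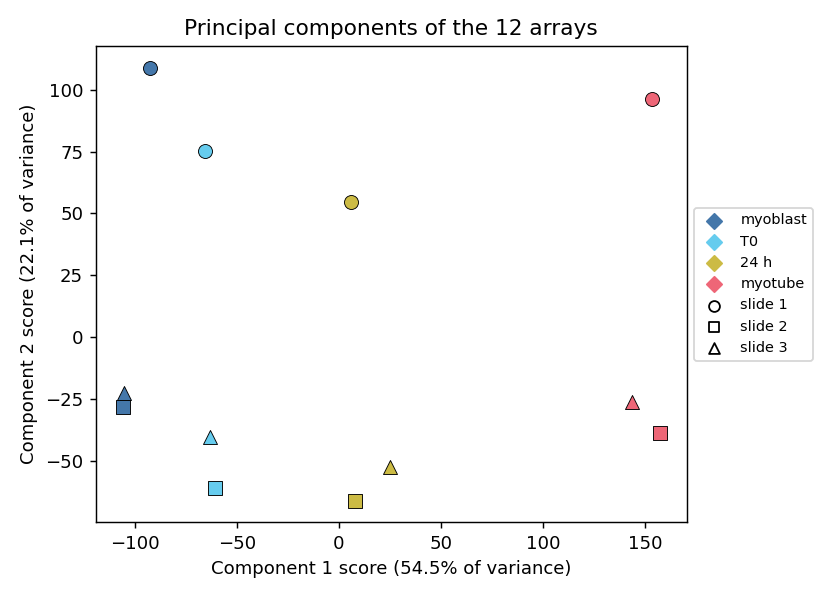
Scores of the 12 arrays on the first and second principal components of the log2 levels of 16159 genes (axes without unit, percent of variance in the labels); colours are stages and symbols are slides. Component 1 runs from -106 for a myoblast array to 157.4 for a myotube array, and on component 2 the 4 arrays of slide 1 lie at 54.6 or above while the other 8 lie below 0.

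Among the regulators fixed beforehand as a panel, Myog (myogenin, probe A_51_P102122), the factor that switches on terminal muscle differentiation, rose 57.8-fold from myoblast to T0 (5.85 ± 0.66, adjusted p = 0.00147) and a further 20.2-fold by 24 h (4.34 ± 0.66, adjusted p = 0.0033). Its last step was 0.45 ± 0.66 (adjusted p = 0.701). Mef2c, a partner of the myogenic factors, was not well above background in myoblasts or at T0, rose at least 9.82-fold by 24 h (adjusted p = 0.00089) and 122-fold from 24 h to myotube (6.93 ± 0.54, adjusted p = 2.18e-05). Myod1, the determination factor, differed between myotube and myoblast by 0.94 (standard error 1.3, adjusted p = 0.624), with levels on slide 1 far below those of the other slides. With the replicate block the difference was 0.94 ± 0.15 (adjusted p = 0.000126). Myf5 fell 7.76-fold from 24 h to myotube (-2.96 ± 0.48, adjusted p = 0.00102). Id3, an inhibitor of the myogenic factors, fell by 4.15 ± 0.74 from myoblast to myotube (adjusted p = 0.000963), while its relative Id1 differed by -1.11 ± 0.61 (adjusted p = 0.179, or 2.49e-06 with the block). The homeobox factor Six1 fell by 1.06 ± 0.29 in the last step (adjusted p = 0.0185), and Six4 differed there by -1.21 ± 0.59 (adjusted p = 0.17, or 0.0011 with the block). Single arrays, left out in fits without the block and so with the slide difference taken in, moved some of these values by over 1.5 times. The T0 change of Myog was 5.13 without myoblast replicate 1 and 6.52 without myoblast replicate 3 or T0 replicate 1. Its 24 h change was 3.67 without T0 replicate 1, and Id3 differed by -3.40 without myotube replicate 1.

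The cyclin-dependent kinase inhibitor Cdkn1a (p21) rose 4.82-fold from T0 to 24 h and 4.35-fold from 24 h to myotube (2.12 ± 0.30, adjusted p = 0.00043), and 41.7-fold from myoblast to myotube. Ccnd3 (cyclin D3) rose 6.54-fold from myoblast to myotube (adjusted p = 0.00248), and the proliferation marker Mki67 fell 48.4-fold (-5.60 ± 0.42, adjusted p = 1.4e-06). Chrna1, a subunit of the acetylcholine receptor, rose 6.34-fold (adjusted p = 0.000132) and Acta1, skeletal alpha-actin, 154-fold (7.27 ± 0.82, adjusted p = 3.53e-05). The Acta1 change was 8.43 without myoblast replicate 1 and 6.57 without myoblast replicate 2. Mymk (listed in the panel by its older name Tmem8c), which cells need in order to fuse, had a myoblast level from 1 array, of slide 1, with the spread taken from the other stages. Its blocked rise was 5.04 ± 0.28 (adjusted p = 5.64e-07), against 6.74 ± 1.42 (adjusted p = 0.00777) without the block, which takes in the slide difference (7.41 without myotube replicate 1, 6.10 without myotube replicate 2). The household genes differed by -1.31 ± 0.81 (Actb, adjusted p = 0.236, or 0.0118 with the block) and 0.38 ± 0.39 (Gapdh, adjusted p = 0.492). Gapdh differed by 0.96 ± 0.39 from 24 h to myotube, a call only with the block (adjusted p = 0.0997, or 0.00312). At T0 against myoblast, Cdkn1a (0.99 ± 0.30, adjusted p = 0.0964, or 0.00538), Chrna1 (1.38 ± 0.36, adjusted p = 0.0611, or 2.14e-05) and Six1 (0.98 ± 0.29, adjusted p = 0.0884, or 0.000387) were calls only with the block. So were Id1 (-1.37 ± 0.61, adjusted p = 0.274, or 8.7e-06), Six4 (1.31 ± 0.59, adjusted p = 0.285, or 0.00174), Myod1 (0.50, adjusted p = 0.906, or 0.0238) and Ccnd3 (0.50 ± 0.56, adjusted p = 0.733, or 0.0224). Myf6 was too dim to be tested, and no probe carried the name Ccnd1.

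**Figure D2:**
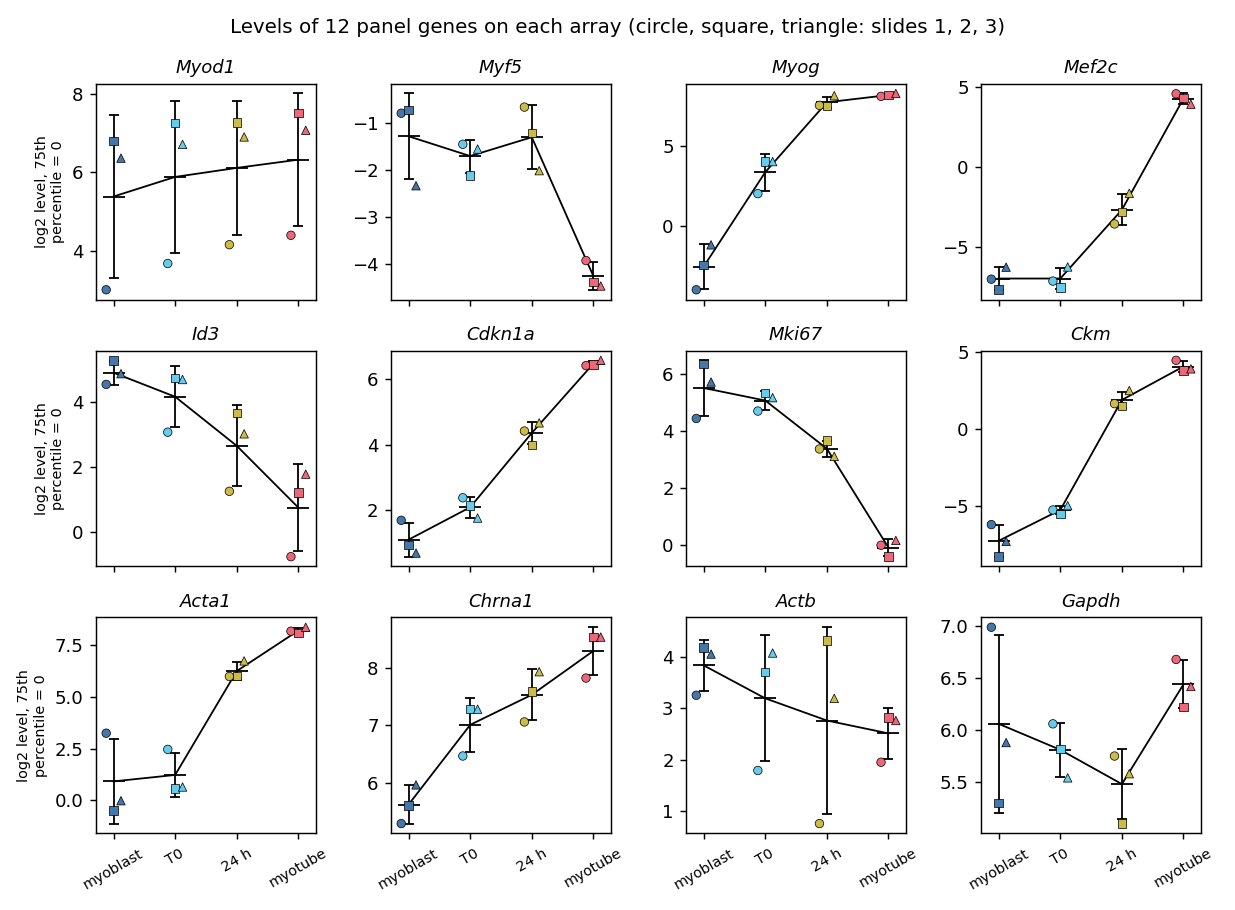
Log2 level (y axis, the array's 75th percentile at 0) of 12 panel genes at the 4 stages (x axis); symbols are single arrays by slide, and the line with bars joins the stage means with 1 SD of 3 arrays. Myog climbs from a mean of -2.50 in myoblasts to 8.15 in myotubes and Mki67 drops from 5.50 to -0.10, while the Myod1 array of slide 1 lies below those of the other slides at each stage.

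Between growing myoblasts and T0, 17 of 51 sarcomere genes rose and 15 of 50 DNA replication genes fell. Besides Myog, the largest rises were Cilp, a cartilage matrix protein (128-fold, or 50.6-fold with myoblast arrays below background at their floor, adjusted p = 0.000121), the RNA-binding protein Rbm24 (22.3-fold, 4.48 ± 0.35, adjusted p = 0.000143), the Notch ligand Dll1 (21.4-fold, 4.42 ± 0.33, adjusted p = 0.000126) and the protease Htra3. The myoblast level of Htra3 came from 1 array, of slide 1, with the spread taken from the other stages, so the blocked change of 3.91 ± 0.26 (adjusted p = 7.35e-06) is given in place of 23.7-fold. Its rank rests on the 23.7-fold alone, since genes such as Tnnt1 (4.20) and Pdlim3 (4.14) changed by more than 3.91. The largest falls were in genes of the epidermal differentiation complex, which encode proteins of the skin barrier: Lce1i (86.7-fold, -6.44 ± 0.71, adjusted p = 0.00133), Lce1g (80.3-fold, adjusted p = 0.00196), Lce1f (at least 12.5-fold, adjusted p = 0.000838) and Prr9 (12.1-fold, or 6.33-fold with the floor, adjusted p = 0.0254). The Lce1 genes are near-identical copies, so which of them a probe measured is uncertain. The endocytic receptor Lrp2 fell 11.1-fold (adjusted p = 0.00647). Without myoblast replicate 3 the changes of Lce1i and Lce1g were -5.69 and -5.63. That of Prr9 was -4.26 without T0 replicate 1 and -2.90 without T0 replicate 2 (adjusted p = 0.102).

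Of 51 sarcomere genes tested, 17 rose and 0 fell between myoblast and T0 (27 and 0 adjusted over the list alone, 29 and 0 among all genes with the block), with a median change of 1.47, or 1.41 with genes below background at their bound. Examples were Tnnt1, slow troponin T (18.3-fold, adjusted p = 0.000488), and Pdlim3 (17.6-fold, adjusted p = 0.000381). The list was shifted up (camera, adjusted p = 4.4e-17; adjusted p = 0.069 with an estimated correlation). The embryonic myosin Myh3 differed by 4.76 ± 1.28, a call only with the block (adjusted p = 0.0677, or 0.00072). Of 21 excitation-contraction coupling genes, 6 rose (8 adjusted over the list alone; 11 rose and 1 fell with the block), among them Hrc (7.40-fold, or 4.66-fold with the floor; a change of 3.52 without myoblast replicate 3) and Jsrp1 (6.31-fold). The list's shift had an adjusted p of 1.19e-05, and adjusted p = 0.109 with an estimated correlation. Of 14 neuromuscular junction genes, 2 rose (6 over the list alone, or 9 among all genes with the block): Chrng, the fetal acetylcholine receptor subunit (19.6-fold, 4.29 ± 0.40, adjusted p = 0.000381), and Chrnd (6.21-fold). This list stayed shifted with an estimated correlation (adjusted p = 0.0187), as did the myogenic transcription factors (adjusted p = 0.0234), of which 1 of 20, Myog, rose (3 adjusted over the list alone, 10 among all genes with the block).

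In muscle energy metabolism, 4 of 25 genes rose at T0 (5 adjusted over the list alone; 9 rose and 3 fell with the block), among them Cox8b (at least 13.1-fold, adjusted p = 0.000121) and the muscle glycogen phosphorylase Pygm (at least 4.24-fold, adjusted p = 0.000745). The list's adjusted p was 0.000403, and adjusted p = 0.211 with an estimated correlation. Ckm, muscle creatine kinase, rose at least 1.5-fold (adjusted p = 0.0459). In the dystrophin complex list, 4 of 18 rose (4 over the list alone; 9 rose and 1 fell with the block), including the sarcoglycans Sgcg (6.59-fold, its T0 level from 2 arrays) and Sgca (5.88-fold), with adjusted p = 0.000258 for the list and adjusted p = 0.0624 with an estimated correlation. Of 16 reserve cell and quiescence genes, 4 rose (4 rose and 1 fell over the list alone, 8 and 1 with the block), among them Heyl, a Notch target (16.4-fold, adjusted p = 0.000381), and Spry1 (9.63-fold, adjusted p = 0.00156). The list's adjusted p was 0.000197, and adjusted p = 0.127 with an estimated correlation. Of 28 insulin-like growth factor and TGF-beta family genes, 2 rose, Igfbp4 (9.74-fold) and Igf1 (6.27-fold), and 1 fell, Inhba (3.53-fold). Of these genes 7 rose and 2 fell over the list alone, 13 and 5 with the block, with adjusted p = 0.00675 for the list and adjusted p = 0.262 with an estimated correlation. Of 37 extracellular matrix genes, 1 rose, Col6a1 (8.16-fold; 6 over the list alone, 15 rose and 2 fell with the block), with adjusted p = 0.000164 and adjusted p = 0.343 with an estimated correlation. Of 21 regulators of cell cycle exit, 3 rose (5 over the list alone; 10 rose and 6 fell with the block), among them Gadd45a (6.82-fold) and Ccng2 (2.50-fold), with adjusted p = 0.0243 and adjusted p = 0.186 with an estimated correlation. The interferon response list had 0 of 21 genes called by limma (0 over the list alone, 1 at an unadjusted p under 0.05, 5 risen with the block), a median of 0.45 and adjusted p = 0.0306 (adjusted p = 0.297 with an estimated correlation). Under normexp its median was -0.01. The change of Igfbp4 was 3.89 without myoblast replicate 2, and without myoblast replicate 3 those of Igfbp4 and Col6a1 were 2.42 and 2.43 (adjusted p = 0.0765 and 0.151).

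Of 50 DNA replication genes, 15 fell and 0 rose (32 fell over the list alone, 48 among all genes with the block), with Ung (3.74-fold, adjusted p = 0.0192) and Mcm10 (3.29-fold, adjusted p = 0.0469) as the largest called. Of 29 ribosome biogenesis genes, 7 fell (15 over the list alone, 29 among all genes with the block), including Nhp2 (3.06-fold, adjusted p = 0.0222) and Nolc1 (2.58-fold). Both lists stayed shifted with an estimated correlation (adjusted p = 0.0178 and 0.023). Of 52 mitosis genes, 3 fell (20 over the list alone, 37 among all genes with the block), among them Aurka (2.95-fold) and Cdc20 (2.44-fold), with adjusted p = 2e-12 for the list and adjusted p = 0.102 with an estimated correlation. Of 54 oxidative phosphorylation genes, limma called 0 (0 over the list alone, 3 at an unadjusted p under 0.05; 1 rose and 18 fell with the block). The list's shift down was a call only with the block (adjusted p = 0.105, or 0.00553), and with the block was lost at adjusted p = 0.47 with an estimated correlation.

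In total 633 genes changed between myoblast and T0, 394 higher and 239 lower. With the block 5494 did, 2210 higher and 3284 lower, and all 633 were among them. The share of higher calls, 62.2%, was 98.1% with spike-in scaling. In that scaling 1 array weighs heavily. The spike-in level relative to the 75th percentile was 1.79 on myoblast replicate 1, 0.66 and 0.85 on the other myoblast arrays, and 0.60, 0.61 and 0.42 at T0. Of the 35 named genes called here, 19 kept their call whichever array was left out. Prr9, Hrc, Sgcg, Ung, Mcm10, Aurka, Cdc20, Gadd45a, Ccng2, Col6a1, Nhp2, Nolc1, Igfbp4, Igf1, Inhba and Ckm did not. The count was 126 without T0 replicate 2, 254 without T0 replicate 3, 325 without T0 replicate 1, 144 without myoblast replicate 3, 400 without myoblast replicate 1 and 381 without 24 h replicate 2.

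**Figure D3:**
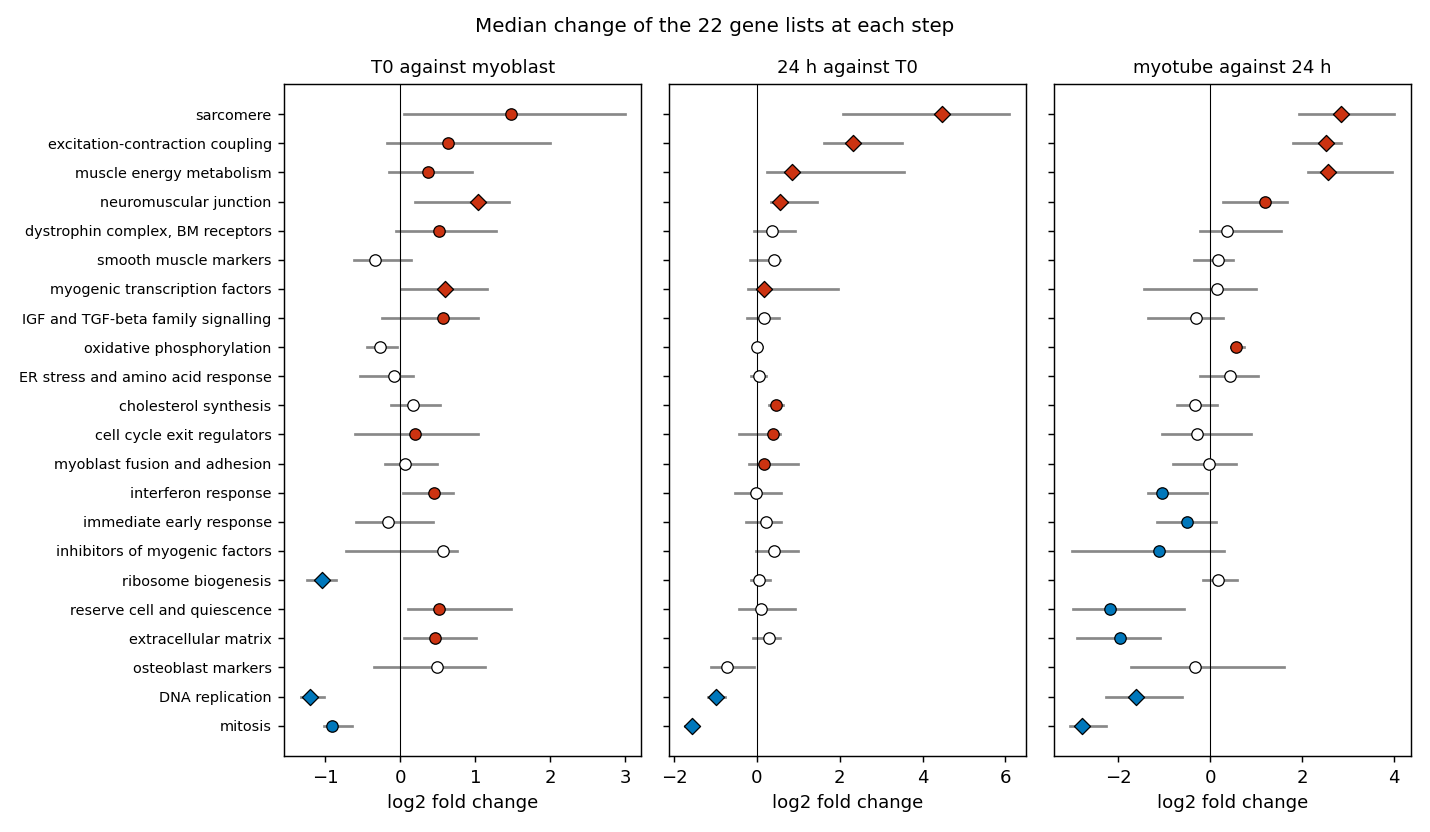
Median log2 fold change (x axis) of the members of 22 gene lists at each step; bars run from the first to the third quartile, filled symbols (red up, blue down) mark lists shifted with the preset correlation, and diamonds those also shifted with an estimated one. The sarcomere median is 1.47, 4.48 and 2.86 over the steps and the mitosis median -0.91, -1.56 and -2.80.

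From T0 to 24 h, 37 of 51 sarcomere genes rose and 31 of 52 mitosis genes fell. The largest rises were Ankrd2, a stretch-responsive titin-binding protein (288-fold, 8.17 ± 0.89, adjusted p = 0.0003), Casq2, a calcium store protein of the sarcoplasmic reticulum (206-fold, 7.69 ± 0.47, adjusted p = 1.02e-05), Itgb1bp2, melusin (175-fold, or 121-fold with the floor, adjusted p = 8.79e-05), Ablim3 (155-fold, adjusted p = 0.00119) and Ckm (140-fold, 7.13 ± 0.48, adjusted p = 1.82e-05). The largest falls were Prl2c5 (18.1-fold, -4.18 ± 0.39, adjusted p = 0.000113) and Prl2c3 (17.0-fold), of the proliferin family whose copies are too alike to be told apart by a probe, then Penk, proenkephalin (12.2-fold, adjusted p = 0.000493), Cdhr1 (12.1-fold) and Car8 (9.75-fold). Single arrays moved 3 of these rises by over 1.5 times. Ankrd2 rose by 9.01 without T0 replicate 3, 8.91 without 24 h replicate 1 and 7.57 without 24 h replicate 3. Itgb1bp2 rose by 6.83 without T0 replicate 2 and 8.26 without T0 replicate 3. Ablim3 rose by 6.60 and 7.90 without T0 replicates 1 and 3, and by 8.21 and 6.47 without 24 h replicates 1 and 3.

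Of 51 sarcomere genes, 37 rose and 1 fell from T0 to 24 h (46 and 1 adjusted over the list alone), with a median of 4.48. Myh3 rose 138-fold (7.11 ± 1.28, adjusted p = 0.00884), Myom1 120-fold (81.4-fold with the floor, 6.90 ± 0.52, adjusted p = 3.05e-05) and Acta1 31.9-fold (adjusted p = 0.00553). The change of Myh3 was 6.17 without T0 replicate 1, 7.82 without T0 replicate 3 and 6.80 without 24 h replicate 3 (adjusted p = 0.0526), and that of Acta1 5.61 without T0 replicate 1. Mylk2, the skeletal myosin light chain kinase, fell 2.55-fold (adjusted p = 0.00821). Of 21 coupling genes, 11 rose (19 over the list alone; 18 among all genes with the block), including Hrc (81.6-fold, 6.35 ± 0.56, adjusted p = 8.16e-05). Of 25 muscle energy genes, 11 rose (13 rose and 1 fell over the list alone), including Cox6a2, a muscle cytochrome oxidase subunit (85.8-fold, adjusted p = 0.00031). Of 14 neuromuscular junction genes, 3 rose (5 over the list alone; 8 with the block), among them Chrng (5.80-fold) and Dok7 (4.15-fold, adjusted p = 0.00089). Of 20 genes listed as myogenic transcription factors, 5 rose (5 over the list alone), including the muscle LIM protein Csrp3, counted in that list (at least 83.8-fold, adjusted p = 1.02e-05). All these lists stayed shifted with an estimated correlation, as did both proliferation lists. Of 52 mitosis genes, 31 fell (47 over the list alone; 52 with the block), with Bub1b (4.95-fold, adjusted p = 0.0438) and Espl1, separase (4.77-fold, adjusted p = 0.0066). Of 50 DNA replication genes, 8 fell (25 over the list alone; 46 with the block), with Tk1 (3.78-fold, adjusted p = 0.00184) and Mcm5 (3.17-fold). Mki67 fell 3.21-fold (adjusted p = 0.0485).

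Fusion and adhesion, cell cycle exit and cholesterol synthesis were shifted up at 24 h with the preset correlation alone. In fusion and adhesion, 3 of 28 genes rose (6 rose and 1 fell over the list alone; 10 rose and 3 fell with the block), with Cav3, caveolin 3 (42.8-fold, 5.42 ± 0.28, adjusted p = 9.8e-06), and the myostatin antagonist Fst (27.3-fold, adjusted p = 0.000258; a change of 5.39 without 24 h replicate 1). The list had adjusted p = 0.0269, and adjusted p = 0.371 with an estimated correlation. Of 21 regulators of cell cycle exit, 3 rose (3 over the list alone; 6 rose and 3 fell with the block), led by Cdkn1c, p57 (19.1-fold, 4.25 ± 0.37, adjusted p = 8.03e-05), with adjusted p = 0.0269, and adjusted p = 0.186 with an estimated correlation. Cholesterol synthesis had 0 of 24 genes called by limma (0 over the list alone, 1 higher and 1 lower at an unadjusted p under 0.05; 6 rose and 1 fell with the block), a median of 0.45, adjusted p = 0.0356, and adjusted p = 0.601 with an estimated correlation. The dystrophin complex list, with 1 of 18 genes risen (2 over the list alone; 6 rose and 1 fell with the block), was shifted only with the block (adjusted p = 0.0789, or 0.0103), and with the block not at adjusted p = 0.164 with an estimated correlation.

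In total 674 genes changed from T0 to 24 h, 450 higher and 224 lower. With the block 3123 did, 1646 higher and 1477 lower, and all 674 were among them. The share of higher calls was 66.8%, or 83.9% with spike-in scaling. Mymk, with a T0 level from 1 array of slide 1, differed by 6.17 ± 1.42 (adjusted p = 0.0698) and with the block by 4.47 ± 0.28 (adjusted p = 1.55e-05). Id3 (-1.52 ± 0.74, adjusted p = 0.447, or 0.0051), Chrna1 (0.52 ± 0.36, adjusted p = 0.739, or 0.0148) and Ccnd3 (0.51 ± 0.56, adjusted p = 0.947, or 0.034) were also calls only with the block. Of the 41 named genes called, 36 kept their call whichever array was left out, and Myh3, Bub1b, Mki67, Gsta2 and Ndrg2 did not. The count was 326 without 24 h replicate 3, 421 without 24 h replicate 2 and 386 without T0 replicate 3.

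From 24 h to myotube, which compares whole cultures with lifted myotubes, 42 of 51 sarcomere genes rose and 50 of 52 mitosis genes fell. Otud7a, a deubiquitinase, and Myot, myotilin of the Z-disc, were not well above background at 24 h and rose at least 246-fold (adjusted p = 3.93e-06) and at least 371-fold (adjusted p = 3.49e-06). Casq1, the calcium store protein of fast fibres, rose 249-fold (165-fold with the floor, 7.96 ± 0.76, adjusted p = 4.87e-05), the titin cap Tcap 175-fold (7.45 ± 0.43, adjusted p = 4.68e-06) and the fast myosin Myh4 166-fold (7.37 ± 1.31, adjusted p = 0.0018). Skeletal myosins are close in sequence, so cross-hybridisation between them cannot be ruled out. The largest falls were Nefl, a neurofilament (144-fold, or 68-fold with the floor, -7.17 ± 0.55, adjusted p = 2.08e-05), the water channel Aqp1 (45.4-fold, adjusted p = 0.000792), the adaptor Blnk (37.2-fold, adjusted p = 3.57e-05), pleiotrophin, Ptn (32.7-fold, or 14.8-fold with the floor), and the hyaluronan synthase Has1 (32.4-fold). The change of Casq1 was 7.01 without 24 h replicate 2 and that of Myh4 7.99 without 24 h replicate 3. Without myotube replicate 1 those of Nefl, Ptn and Aqp1 were -7.80, -5.79 and -4.73. That of Aqp1 was -6.09 without 24 h replicate 1 and -6.20 without myotube replicate 3.

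Of 51 sarcomere genes, 42 rose and 0 fell from 24 h to myotube (46 and 0 adjusted over the list alone). Coupling genes rose in 18 of 21 (19 over the list alone), including parvalbumin, Pvalb (17.9-fold, adjusted p = 0.000666). Genes listed under muscle energy rose in 20 of 25 (22 over the list alone). They include the mitochondrial creatine kinase Ckmt2 (29.8-fold, adjusted p = 3.72e-05) and, counted in that list, the ADP-ribosyltransferase Art1 (26.5-fold). These 3 lists stayed shifted with an estimated correlation (adjusted p = 0.0306, 0.0299 and 0.0199). The change of Pvalb was 3.45 without 24 h replicate 2 and 4.75 without 24 h replicate 3. Of 14 neuromuscular junction genes, 4 rose and 1 fell (the same counts over the list alone; 10 and 1 with the block), with Ache, acetylcholinesterase (7.22-fold), Chrnd (3.63-fold) and, falling, agrin, Agrn (2.71-fold). The list had adjusted p = 0.0155, and adjusted p = 0.116 with an estimated correlation. Of 54 genes listed under oxidative phosphorylation, 9 rose (1 over the list alone, 46 among all genes with the block), with a median of 0.56. Ndufs4 rose 2.74-fold and Ogdh, a citric acid cycle enzyme counted in the list, 2.64-fold. The list had adjusted p = 2.98e-06, and adjusted p = 0.343 with an estimated correlation.

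Mitosis genes fell in 50 of 52 (51 over the list alone), with a median of -2.80; Melk fell 12.2-fold (-3.61 ± 0.35, adjusted p = 5.63e-05), and survivin, Birc5, 15.5-fold with a myotube level from 1 array and the spread of the other stages (adjusted p = 0.0196; blocked change -2.76 ± 0.19). DNA replication genes fell in 27 of 50 (37 over the list alone), with Chaf1b (8.91-fold) and Uhrf1 (8.30-fold, adjusted p = 0.00179). Both stayed shifted with an estimated correlation (adjusted p = 0.0248 and 0.0368). Of 37 extracellular matrix genes, 22 fell and 0 rose (28 over the list alone), with the collagens Col4a1 (12.8-fold, adjusted p = 0.00101) and Col5a3 (11.2-fold). Of 16 reserve cell genes, 9 fell and 1 rose (10 and 1 over the list alone), with Notch3 (16.1-fold, -4.01 ± 0.42, adjusted p = 8.06e-05), Gas1 (13.5-fold) and, rising, Spry1 (2.39-fold). The matrix list had adjusted p = 7.17e-09, and adjusted p = 0.145 with an estimated correlation. The reserve cell list had adjusted p = 0.000223, and adjusted p = 0.127 with an estimated correlation. The change of Birc5 was -4.58 without 24 h replicate 1, which sets slides 2 and 3 at 24 h against slide 1 in myotubes. Without myotube replicate 1 those of Col5a3 and Gas1 were -2.85 and -2.89, and that of Gas1 was -4.39 without myotube replicate 3.

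Of 17 inhibitors of myogenic factors, 6 fell and 1 rose (7 and 3 over the list alone; 10 and 5 with the block), among them Heyl (11.3-fold lower) and Bhlhe40 (3.40-fold higher), with adjusted p = 0.0456, and adjusted p = 0.144 with an estimated correlation. Of 21 interferon response genes, 7 fell (10 over the list alone; 13 with the block), with Oasl2 (12.7-fold) and Ifih1 (6.94-fold, or 4.1-fold with the floor), adjusted p = 0.01, and adjusted p = 0.202 with an estimated correlation. Of 34 immediate early and growth factor response genes, 11 fell and 3 rose (13 and 3 over the list alone, 16 and 5 with the block), with Hmga2 (19.9-fold lower), Plaur (10.3-fold lower, adjusted p = 1.47e-05) and Nr4a1 (3.52-fold higher). That list's shift was lost with the block (adjusted p = 0.0438, or 0.0599) and with the estimate (adjusted p = 0.144 with an estimated correlation). Without myotube replicate 1 the changes of Oasl2 and Hmga2 were -3.03 and -3.15, and without myotube replicate 3 those of Hmga2 and Ifih1 were -5.12 and -2.03. That of Ifih1 was -3.42 without myotube replicate 2.

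In total 4382 genes changed from 24 h to myotube, 1694 higher and 2688 lower. With the block 9335 did, 4279 higher and 5056 lower. The share of higher calls, 38.7%, was 25.5% with spike-in scaling and 49.6% with normexp background correction. Acta1 differed by 1.96 ± 0.82, Mymk by 1.44 ± 1.01, Id3 by -1.90 ± 0.74, Chrna1 by 0.76 ± 0.36 and Id1 by 0.30 ± 0.61, calls only with the block (adjusted p = 0.0162, 0.00124, 0.00027, 0.000301 and 0.039). Of the 53 named genes called, 48 kept their call whichever array was left out, and Birc5, Ndufs4, Spry1, Ccnd3 and Six1 did not.

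Myotubes and growing myoblasts, the ends of the course, differed in 6655 genes, 2867 higher and 3788 lower in myotubes (11185 with the block, 4853 and 6332). The share of higher calls, 43.1%, was 52.9% with spike-in scaling, where higher calls were the majority. That share, too, rests in part on the high spike-in level of myoblast replicate 1. Myh4 rose 28800-fold (14.81 ± 1.31, adjusted p = 5.28e-06), the myosin light chain Myl3 18000-fold (14.14 ± 0.78, adjusted p = 3.76e-07), Mybph 10900-fold, the perinatal myosin Myh8 10900-fold and myoglobin, Mb, 10300-fold (13.33 ± 0.61, adjusted p = 4.91e-08). In myoblasts these genes were well above background on 1 (Myh4, Myl3 and Mybph) or 2 (Myh8 and Mb) of 3 arrays, so their folds start close to the floor of the arrays. With the floor, Myh4 rose 10400-fold and Myl3 8530-fold. A second Myl3 probe fell by 1.48 ± 0.29 (adjusted p = 0.00279, limma with the block). The largest falls were Prl2c5 (at least 1100-fold, adjusted p = 1.71e-08), Nefl (1040-fold, or 493-fold with the floor, adjusted p = 1.54e-07), Prl2c3 (at least 796-fold), Lce1g (287-fold, or 172-fold with the floor) and Lce1i (171-fold, or 80.7-fold). Without myoblast replicate 2 the changes of Myh4, Myl3 and Mybph were 14.12, 13.46 and 12.81. Without myoblast replicate 3 those of Myh4, Myh8, Lce1g and Lce1i were 15.55, 14.01, -7.47 and -6.67. That of Nefl was -10.65 without myotube replicate 1, that of Lce1g -7.50 without myotube replicate 2 and that of Lce1i -8.07 without myotube replicate 3.

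Between the ends, 50 of 51 sarcomere genes rose (50 over the list alone), with a median of 9.64, or 9.38 with bounds, and so did 21 of 21 coupling genes (21 over the list alone), including Hrc (7960-fold, or 5020-fold with the floor) and Casq2 (at least 3540-fold). Muscle energy genes rose in 23 of 25 and fell in 1 (the same over the list alone): Cox6a2 rose 2520-fold, and Pdk4, which restrains pyruvate oxidation, fell 5.22-fold (-2.38 ± 0.47, adjusted p = 0.00197). Neuromuscular junction genes rose in 11 of 14 and fell in 1 (12 and 1 over the list alone), with Chrng 374-fold and Chrnd 39.7-fold higher and Agrn 2.36-fold lower. Of 52 mitosis genes, 51 fell (52 over the list alone), with Espl1 (82.9-fold) and Pbk (81.8-fold), and of 50 DNA replication genes, 47 fell and 1 rose (49 and 1 over the list alone), with Mcm10 (59.0-fold), Tk1 (53.0-fold, -5.73 ± 0.27, adjusted p = 5.55e-08) and, rising, the transcription factor E2f2 (4.67-fold, adjusted p = 0.00146). All 6 lists stayed shifted with an estimated correlation. Without myoblast replicate 3 Hrc rose by 13.59 and Cox6a2 by 11.93, and without myoblast replicate 2 Cox6a2 rose by 10.31.

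The dystrophin complex list, with 11 of 18 genes higher and 3 lower (12 and 3 over the list alone), had adjusted p = 0.000532, and adjusted p = 0.069 with an estimated correlation. Sgcg rose 190-fold, Sgca 82.5-fold and Dtnb fell 10.4-fold. Ribosome biogenesis, with 10 of 29 lower (9 over the list alone; 19 lower and 1 higher with the block), had adjusted p = 0.0403, and adjusted p = 0.371 with an estimated correlation. Gar1 fell 5.22-fold and Fbl, fibrillarin, 3.37-fold. Oxidative phosphorylation, with 6 of 54 higher (5 over the list alone; 26 higher and 2 lower with the block), had adjusted p = 0.00933, and adjusted p = 0.602 with an estimated correlation. Ndufs2 rose 2.59-fold and Ndufs4 2.38-fold. Extracellular matrix genes (4 of 37 higher, 14 lower; 4 and 15 over the list alone) and myogenic transcription factors (6 of 20 higher, 5 lower; 7 and 5 over the list alone, 10 and 5 with the block) were shifted, down and up, only with the block (adjusted p = 0.0615, or 0.0292, and 0.0553, or 0.0495). With the block they had adjusted p = 0.605 and 0.263 with an estimated correlation. The 41 named genes called included 39 that kept the call whichever array was left out, all but Fbl and Ndufs4. Blocked fits with an estimated correlation left camera with 0 shifted lists in each of the 4 comparisons. At an unadjusted p under 0.05 there were 6, 7, 4 and 6.

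A transient rise, a fitted level at least 2-fold higher at 24 h than both at T0 and in myotubes, was found for 43 genes (167 with the block); with dim stages at their floor, 39 of them were at least 2-fold higher in both steps. The 6 named ones include the matricellular genes Ccn3 (at least 17.3-fold up, then at least 13.0-fold down) and Ccn5 (16.6-fold up, 8.05-fold down), the protease Adamts15 (at least 21.1-fold up, 10.7-fold down) and the matrix genes Sparcl1 (11.7-fold up, 12.9-fold down) and Prelp (10.6-fold up, 5.99-fold down). The cell cycle inhibitor Cdkn1c rose 19.1-fold and fell 7.16-fold (-2.84 ± 0.37, adjusted p = 0.000305). A transient fall was found for 20 genes (62 with the block; 19 of the 20 at least 2-fold with the floor), led by the glutathione transferases Gsta1 (7.38-fold down, then 16.1-fold up, 4.01 ± 0.30, adjusted p = 1.82e-05), Gsta2 (6.48-fold down, 11-fold up) and Mgst2 (6.03-fold down, 5.75-fold up). Cd24a fell 6.02-fold and rose 23.2-fold (4.54 ± 0.27, adjusted p = 6.07e-06), Ndrg2 fell 4.01-fold and rose 5.70-fold, and Serpinb6b fell 3.74-fold and rose 5.24-fold. Gsta1 and Gsta2 are close copies and not safely told apart. The second change of Ccn5 was -2.31 without myotube replicate 1 and -3.79 without myotube replicate 3, that of Sparcl1 -4.36 without myotube replicate 3, and the first change of Gsta2 -3.34 without T0 replicate 2. Without 24 h replicate 3, 24 h replicate 2, T0 replicate 3 or T0 replicate 1 the rises numbered 11, 22, 25 and 26; without 24 h replicate 2, 24 h replicate 3 or T0 replicate 3 the falls numbered 11, 12 and 12. The second step of these genes also crosses from whole cultures to lifted myotubes.

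Osteoblast markers (7 tested) and smooth muscle and myofibroblast markers (9 tested) were shifted in none of the 4 comparisons by camera, with 0 calls also with an estimated correlation. For osteoblast markers the smallest adjusted p was 0.0513, at 24 h against T0, where 1 of 7 fell (1 over the list alone, 2 with the block). The unadjusted p was 0.0268. From myoblast to myotube 2 osteoblast markers rose and 4 fell, with a median of -1.97, and 2 smooth muscle markers rose and 3 fell (5 and 3 with the block). For smooth muscle markers the smallest adjusted p was 0.325, with an unadjusted p of 0.251. Adipocyte markers and endothelial and blood cell markers had 4 tested members each, too few for the list test. From myoblast to myotube 1 rose and 1 fell in each (1 and 2 with the block for adipocyte markers). The endoplasmic reticulum stress and amino acid response list (24 tested) was not shifted at any step, with 7 genes higher and 3 lower in myotubes than in myoblasts (the same over the list alone, 11 and 7 with the block) and adjusted p = 0.3.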

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

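The added alternatives, chosen after seeing the data, are normexp on the median signal, slides 2 and 3 only, and the block with quantile normalization. The results are, in order, genes changed over the 4 stages, genes changed, T0 against myoblast, genes changed, 24 h against T0, genes changed, myotube against 24 h, genes changed, myotube against myoblast, genes with a transient rise at 24 h and genes with a transient fall at 24 h. With the replicate block these counts were 13066, 5494, 3123, 9335, 11185, 167 and 62; with scan day as a block 11523, 3720, 2131, 8073, 10165, 131 and 55; with the block and quantile normalization 13013, 5115, 3065, 9334, 11196, 142 and 66. Blocks take the part shared by same-numbered arrays out of the spread, and beyond those given with each comparison the replicate block changed no call of a list. Genes changed between myoblast and T0 were 1086 on slides 2 and 3 only, 261 with normexp, 243 with the deposited table, 304 without the filter, 80 with only the 6 arrays compared and 127 with treat against a minimum change. At 24 h against T0 they were 391 with spike-in scaling, 432 with normexp, 296 with probes detected on all arrays (fewer genes tested), 405 with only the 6 arrays compared and 352 with treat against a minimum change, and at myotube against 24 h 2820 with probes detected on all arrays and 2680 with treat against a minimum change. Transient rises numbered 22 with normexp and 14 with probes detected on all arrays; transient falls 10 with spike-in scaling, 10 with normexp and 11 with the deposited table. Lists shifted with an estimated correlation were 4 of 22 at T0 against myoblast and 5 at myotube against 24 h. The planned normexp on the mean signal was not run, and the slide block is the replicate block. Where construction (fewer arrays, genes or a stricter test) does not show the cause, the cause was not tested.

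Leaving out 1 array at a time gave 5239 to 6374, 126 to 582, 326 to 742, 3287 to 4680, 5422 to 6697, 11 to 56 and 11 to 20 for these counts, and 13 to 15, 7 to 14, 10 to 12 and 8 to 11 shifted lists. The 214 named values had 5481 values under alternatives: 5126 kept direction and side of the threshold, 261 lost the call, 94 gained it and 0 changed direction past the threshold. Signal over background limits the fold of genes dim at one stage: it is a bound where no array was above background, and otherwise rests partly on values below it.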

Other observations

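The tests of myotube enrichment, array position and Lce1 copies, those of other splits of the arrays, the comparison of probes of 1 gene, and the lists of ubiquitin ligase, imprinted, epidermal and keratinocyte genes were chosen after the results were seen. Of 16 muscle ubiquitin ligase and ASB genes tested, 3 rose and 1 fell from myoblast to T0 (8 and 1 with the block). From T0 to 24 h 5 rose (9 with the block), and from 24 h to myotube 9 rose and 1 fell (13 and 1 with the block). No test of this list or of the imprinted one is given, since both were chosen with the results in view. Trim63 (MuRF1), known from muscle atrophy, rose at least 6.02-fold by T0 and by 5.40 ± 0.55 by 24 h (adjusted p = 0.000209), and Klhl41 rose 12.5-fold by T0 and by 5.34 ± 0.55 by 24 h (adjusted p = 0.000215). Asb14 rose at least 44.1-fold from 24 h to myotube (adjusted p = 1.14e-05), having been above background on 0 arrays before, whereas Asb4 fell 5.09-fold by T0 (adjusted p = 0.0263) and Fbxo32, the other well-known atrophy ligase, fell by 1.41 ± 0.35 from 24 h to myotube (adjusted p = 0.0122). The Asb4 call was lost without either of myoblast replicates 2 and 3 or any T0 array (adjusted p up to 0.129, changes of -2.09 to -2.52), and that of Fbxo32 without 24 h replicate 1 (-1.14, adjusted p = 0.0505); with the block both were called (adjusted p = 0.00249 and 3.31e-05).

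Of 12 imprinted genes tested, 3 rose from myoblast to T0 (9 rose and 1 fell with the block) and 4 rose from T0 to 24 h. From 24 h to myotube 1 rose and 4 fell (3 and 5 with the block). Mest rose 12.1-fold by T0 (adjusted p = 0.0239) and fell by 4.27 ± 0.73 from 24 h to myotube (adjusted p = 0.00136), back to its myoblast level within 0.03 ± 0.73. Peg3 rose 3.21-fold by T0 (adjusted p = 0.0395), with later steps of -0.19 ± 0.39 and -0.16 ± 0.39. Igf2 rose by 3.85 ± 0.79 by 24 h and by 3.13 ± 0.79 to myotube (adjusted p = 0.0189 and 0.0127), after a step of 1.66 ± 0.79 from myoblast to T0 that was a call only with the block (adjusted p = 0.314, or 5.78e-05). From myoblast to myotube it rose by 8.64 ± 0.79, and Igf2r rose by 1.72 ± 0.24 by 24 h (adjusted p = 0.00185). Single arrays decided several of these calls in the fit without the block. That of Mest at T0 was lost without myoblast replicate 1 (2.87, adjusted p = 0.0576), myoblast replicate 3 (3.94, adjusted p = 0.0671), T0 replicate 2 (3.12, adjusted p = 0.109) or T0 replicate 3 (3.36, adjusted p = 0.0824), and its change was 4.30 without T0 replicate 1. That of Peg3 was lost without any of 10 arrays, with changes of 1.29 to 1.89 and adjusted p up to 0.15. The 24 h call of Igf2 was lost without T0 replicate 1 (3.28, adjusted p = 0.0713), 24 h replicate 2 (3.69, adjusted p = 0.0758) or 24 h replicate 3 (3.26, adjusted p = 0.0995), and its change was 4.59 without 24 h replicate 1. The last step of Igf2 was not called without myotube replicate 3 (2.61, adjusted p = 0.0543), and was 2.39 without 24 h replicate 1 and 3.72 without 24 h replicate 3 or myotube replicate 1. With the block these 4 steps were called (adjusted p = 2.58e-06, 4.03e-05, 4.12e-08 and 1.21e-07).

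Probes of 1 gene moved in opposite directions, each by at least 2-fold, in 3 genes from myoblast to T0 and 2 from T0 to 24 h (limma with the block). There were 24 such genes from 24 h to myotube and 39 from myoblast to myotube. The fit without the block, with no minimum change, gave 0, 0, 16 and 28 genes in the same order. In Pdlim5, a Z-disc protein, 2 probes rose by 2.19 ± 0.41 and 1.82 ± 0.26 from 24 h to myotube while 3 fell by 1.70 ± 0.44, 3.00 ± 0.26 and 3.52 ± 0.36. In Pdlim7, 2 rose by 1.62 ± 0.28 and 1.15 ± 0.21 and 2 fell by 3.21 ± 0.20 and 3.25 ± 0.18. Pde4dip (myomegalin) had 3 probes that rose by 2.53 to 3.13 and 2 that fell by 1.66 ± 0.38 and 2.28 ± 0.22, and Asph had 1 that rose by 3.45 ± 0.31 beside 2 that fell by 1.1 ± 0.20 and 1.35 ± 0.37. Where these probes lie in the transcripts was not analysed here, and the report's value for such a gene is that of its brightest probe.

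Muscle genes rose from 24 h to myotube, the step at which reserve cells were removed. If that removal were the whole cause, sarcomere and coupling genes already at least 8-fold up at 24 h, to which reserve cells at their T0 level add little, would rise by 1 common factor. The 40 such genes measured at both stages rose by 1.11 (Myh3) to 7.37 (Myh4), with an SD of 1.43, 4.4 times their median standard error of 0.32. They thus did not rise by 1 common factor. The test takes brightness to follow RNA amount alike in all probes, which was not checked. The mean level of Myh3 was 7.73 at 24 h and 8.84 in myotubes, that of Myh4 0.24 and 7.62. A weaker response of bright spots would also widen the spread, so enrichment as the whole or a part of the cause stays open. Array position differed with stage. A position effect blind to gene function would leave the sarcomere list among lists of like brightness, but 100% of 10000 such random lists had a median below its 2.86, the highest being 0.49. The list was already known to be shifted up at this step, so this restates that shift. It speaks only against an effect blind to gene function and cannot separate position from stage. Further maturation of the fibres between 24 h and 96 h may be the biological part, as a hypothesis that neither test (4.4 and 100) decides and that was not tested itself.

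Of 36 epidermal differentiation complex genes on the array, 16 were above background in myoblasts; of 16 tested, 5 fell by T0 (8 with the block). The list was drawn up because Lce1 genes and Prr9 were among the largest falls, so no test of it is given. Keratinocytes among the myoblasts would bring their abundant keratins and junction genes; of 19 such genes on the array, 5 were above background on all 3 myoblast arrays and 2 of them fell by at least 1 on the log2 scale (Krt5, -1.23 from a level of -4.40, and Krt14, -1.74 from 0.00). With the block 3 of the 5 fell, Sfn (-0.50) being the other. Krt16, not counted as above background on all 3 myoblast arrays, changed by -1.33 from a level of -1.70. The 2 of 19 genes above background and falling by at least 1 lie under the share set before this test, which argues against keratinocytes. With 5 of 19 genes above background, that rests mainly on the genes not detected. Outside the Lce family 4 genes fell with the block, Lor (-3.02), Prr9 (-3.59), Sprr1a (-1.32) and Sprr2a1 (-0.86). Of these, Lor and Prr9 were called without it, and the call of Lor was lost without T0 replicate 2 (-2.56, adjusted p = 0.0523). These falls say nothing on whether Lce1 probes read each other's transcripts. The Lce1 probes did not all move alike. Lce1b did not fall by T0 (-0.25, adjusted p = 0.663 in limma with the block), and Lce1f rose at least 4.99-fold from 24 h to myotube. They thus did not all read 1 transcript, but cross-hybridisation between the near-identical Lce1 probes stays open for the Lce1 falls. A candidate explanation also left open, and not tested, is regulation of the complex in growing C2C12 cells.

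Slide 1 stood apart from slides 2 and 3 at every stage: 9633 genes differed (limma, stages in the same fit), and of 22 lists oxidative phosphorylation was shifted, lower on slide 1 by a median of 0.58 (adjusted p = 0.00716). A smooth curve of the mean level explained 13% of the variance of the slide's deviation, between the bounds of 10% and 50% set beforehand. A brightness-dependent scanning or hybridisation effect could thus account for part. For the rest, slide 1, its scan day and replicate 1 coincide, so slide, scan day and a possible difference of culture cannot be told apart. No biological explanation was tested.

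Of 100 splits of the 12 arrays into 4 groups of 3, 1, the real one, gave as many genes changed over the 4 stages (6482, highest other 5666). A share of 1 in 100 is the smallest these splits allow, and they ignored the pairing by slide. They speak against a random grouping for that count without excluding it. The comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05. Fitted on 6 arrays, the real split gave 80, 405, 3707 and 5557 changed genes in the order T0 against myoblast, 24 h against T0, myotube against 24 h and myotube against myoblast, and the highest other 37, 31, 3 and 0; 1 split, the real one, reached the count in each. The real split parts all 3 pairs of a slide, as do 3 others, and these gave 0 genes in each comparison. Each of these 3 exchanges the stages on 1 slide, so a real stage difference would itself widen the spread within the groups. Their 0 genes therefore decide nothing on chance. Shifted lists numbered 14, 13, 10 and 11 in the real splits and up to 14, 12, 13 and 12 in others, with 2, 1, 4 and 2 of 10 splits reaching the real count. For T0 against myoblast the other split with 14 lists exchanges the arrays of slide 1, and for myotube against 24 h the one with 13 exchanges those of slide 2; the blocked fits of all arrays gave 15, 11, 11 and 11. Others reaching the real count were 12 and 11 lists for myotube against 24 h, in splits parting 1 pair and exchanging slide 3, and 12 for myotube against myoblast, in a split parting 1 pair. Why these splits gave as many lists was not tested.

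Of 100 splits of the 9 arrays of T0, 24 h and myotube, 2 gave as many transient rises (43, highest other 1253) and 5 as many falls (20, highest other 2068). Of 100 splits with 1 array of each slide in each group, 5 gave as many rises (highest other 1304) and 8 as many falls (highest other 2091), but each other split reaching either count had all 3 arrays of T0 or of myotube in the middle group, so real stage differences fix the outcome and it decides nothing on chance, a reading adopted after these splits were seen. The splits without such a group gave at most 1 rise and 0 falls. Among the unrestricted splits, the other 1 reaching the rises had such a group. Of the other 4 reaching the falls, 2 had such a group, and 2 had the 3 arrays of slide 1 there, with 89 and 115 falls. Both shares depend on how many such splits were drawn, so they too decide nothing on chance. Such splits point to a structure of the samples, stage and slide. With the replicate block the real split gave 167 rises and 62 falls.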
